A study of Drosophila melanogaster with 6 samples.

How the data were processed

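Gene expression was measured in pools of Drosophila melanogaster embryos on Affymetrix Drosophila Genome 2.0 arrays, 1-colour arrays hybridized with biotin-labelled RNA. Embryos were collected at 25 °C and were 2 to 4 h old at lysis, per the labels. The brakeless group came from mothers whose germ line was homozygous for a strong brakeless allele, made by FLP/FRT recombination on chromosome arm 2R, and from fathers that carried the same allele over the CyO balancer. The control group came from mothers with germline clones of the unmutagenized FRT chromosome, mated to males with that chromosome. Each group had 3 arrays, described by the labels as biological replicates. The replicate numbers were taken from the sample titles; the description of control replicate 3 carries a different number.

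The deposited values are log2 expression values per probe set, normalized by the authors across the arrays with RMA, per the submitters' processing notes. RMA subtracts a background, gives every array the same distribution of probe intensities and combines the probes of a set, so it compresses differences near the background and hides any difference in total RNA per embryo. The settings and software version of RMA are not given in the sources used here. The scale was read from the values, which lay between 1.98 and 14.3 over all arrays. The table held 18952 probe sets. The 183 Affymetrix control probe sets were left out of the tests and used only to follow hybridization and RNA quality, which left 18769 probe sets. Array data carry no read depth, and the number of arrays limits the precision.

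Probe sets were named from the platform annotation. Of those tested, 13647 had 1 gene symbol, 402 had several and 4720 had none. Gene numbers matched 13544 of the single symbols to the RefSeq genes of Release 6 plus ISO1 MT, with 0 symbols changed, and the other 103 kept the name of the platform annotation. Gene positions are those of that RefSeq assembly. Positions of the probes within the genes were not used here. Gene-level results used the probe set with the highest mean over the 6 arrays for each of 11982 genes, and no gene was named from a probe set with several symbols.

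The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, all 6 arrays), two-sided, with Benjamini-Hochberg adjustment over the 18769 probe sets and a threshold of 0.05. The differences are brakeless minus control on the log2 scale. Intervals are 95% intervals of the moderated fit. Limma's prior held 2.05 degrees of freedom beside 4 residual ones. The test design, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named every sbb probe set, up to 12 genes with the greatest rise and 12 with the greatest fall among those past the threshold with the 3 brakeless arrays on 1 side of the 3 control arrays, up to 4 members of each list past the test, and the gap genes hb, Kr, kni, gt, tll and hkb whatever their result. Only 6 genes qualified as risen. Genes named outside that rule were chosen after their values were seen.

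For 26 lists, covering segmentation, dorsoventral and terminal patterning, maternal transcripts, pole cells, eggshell, older tissues, stress and housekeeping functions, shifts were tested with camera at a preset inter-gene correlation of 0.01. Benjamini-Hochberg adjustment ran over the lists. Camera with an estimated correlation and fry stood beside it. Counts of list members adjusted over the list alone are given beside those adjusted over all probe sets. The chromosome of called genes was compared by Fisher's exact test. Principal components and correlations described the arrays, and exact permutation tests compared single values per array. Intervals of medians came from 10000 bootstrap draws of genes, so they do not measure the spread between arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

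The limma step was tested on simulated data for the brakeless against control comparison, with 200 of 18769 probe sets changed in each of 20 simulations. It recovered 2.5% of changes of 0.5 on the log2 scale, 45.0% of changes of 1, 77.5% of changes of 2 and 86.5% of changes of 3, and 6.0% of its calls were false. A list shifted by 0.5 passed camera at an unadjusted p of 0.05 in 95.0% of the simulations and an unshifted list in 0%. The simulated probe sets were drawn independently of each other. These shares therefore do not describe lists whose members vary together across arrays, or a p adjusted over the lists. The simulations also gave 112.5 calls on average, against 26 in the data. The adjusted threshold depends on how many probe sets change, so the recovered and false shares need not hold for the data.

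Alternatives fixed in advance were eBayes with trend and robust, array weights, quantile normalization applied again, centring of each array on its median, filters at the 40th and 60th percentile of mean signal, the replicate number as a block, each array left out in turn, a requirement of 2-fold change, limma's treat against 1.5-fold, 1 probe set per gene, the mean of all probe sets of a gene, and the other list tests. Added after the data were seen were fits with the hybridization spike mean or the mean of the cleared maternal transcripts as a covariate, and a list of testis markers.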

Results

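Transcript levels were measured on 6 arrays, 3 from embryos of brakeless germline clone mothers and 3 from embryos of control germline clone mothers, each array from a separate pool of 2 to 4 h old embryos. This age spans the syncytial blastoderm, cellularization and gastrulation. Brakeless, encoded by the gene sbb, is a nuclear protein known as a transcriptional co-regulator that acts with the corepressor Atrophin, and its loss from the maternal germ line is known to disturb segmentation. The comparison asks which transcripts depend on maternal Brakeless in the early embryo. By the cross, some embryos of each brakeless pool also lacked the zygotic gene and the others carried the CyO balancer. The median log2 value was 3.59 to 3.73 across the arrays. Mean correlations with the other arrays ran from 0.979 to 0.986 for 5 arrays, and control replicate 3 stood lower at 0.964.

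The targeted gene was examined first. The sbb gene lies on 2R at 18278198 to 18357296 (Release 6 plus ISO1 MT) and is represented by 3 probe sets. On probe set 1635211_at the log2 level was 4.80 ± 0.47 in brakeless embryos and 6.26 ± 0.39 in control embryos (SD, n = 3 arrays each), a difference of -1.46 (SE 0.30, 95% interval -2.20 to -0.73). Each brakeless array, at 5.33, 4.45 and 4.61, lay below every control array, at 6.01, 6.71 and 6.06. The difference did not pass the test over all probe sets (limma adjusted p = 0.320, unadjusted p = 0.00268). The other 2 probe sets were dim in both groups. Probe set 1624001_at read 4.11 ± 0.18 against 4.03 ± 0.24, a difference of 0.08 (interval -0.33 to 0.49), and 1626352_at read 3.69 ± 0.20 against 3.58 ± 0.34, a difference of 0.11 (interval -0.39 to 0.60), both with a limma adjusted p of 0.998. The positions of these probe sets relative to the lesion were not analysed here, so they do not settle whether the allele removes the transcript.

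Between the groups, 6 probe sets were higher and 20 were lower in brakeless embryos, and all 26 differed by at least 2-fold. They named 22 genes, of which 6 rose and 16 fell, and in each of the 22 the 3 brakeless arrays lay apart from the 3 control arrays. The greatest rise was that of Cyp12a4, a mitochondrial cytochrome P450, which was 11.6-fold higher over a control level (3.77) near the median of all probe sets (3.67). The greatest fall was that of CG14314, which was 24.5-fold higher in control than in brakeless embryos. The median size of the 26 changes was 2.18 on the log2 scale, with a range from 1.30 to 4.61. Over all probe sets 898 had an unadjusted p under 0.05, where chance alone gives 938, and 1893 (10.1%) had groups that did not overlap, where chance gives 10%. The number of calls moved when an array was left out: limma called 0 probe sets without brakeless replicate 1, brakeless replicate 2 or control replicate 2 (662, 532 and 1427 at an unadjusted p under 0.05), 6 without brakeless replicate 3, 8 without control replicate 1, and 33 (10 higher and 23 lower) without control replicate 3, of which 19 were among the 26. The log2 differences themselves were less affected, from 3.31 to 3.86 for Cyp12a4, 3.13 to 3.29 for CG32795 and -4.86 to -4.43 for CG14314. These genes were picked on the same arrays for large differences with little spread, so this says nothing about their stability. Quantile normalization applied again gave 8 higher and 15 lower, of which 16 were among the 26. Of the genes named by the rule it ended the calls of CG3032, CG17560, CG2993, ord, Cyp6d2, CG10916, CG1894 and CG32773. Their limma adjusted p then ran from 0.0576 for Cyp6d2 to 0.289 for CG3032. Their differences stayed close (-2.27 after and -2.32 before for Cyp6d2, -2.79 after and -2.83 before for ord).

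Among the genes that rose, Cyp12a4 (3R, 19135158 to 19137136) went from 3.77 ± 0.56 in control embryos to 7.31 ± 0.08 in brakeless embryos (SD, n = 3 each), a log2 difference of 3.54 (SE 0.28, limma adjusted p = 0.0210). CG32795 on the X chromosome (2782906 to 2790567) had the smallest adjusted p of all probe sets and rose from 5.23 ± 0.16 to 8.43 ± 0.15, a difference of 3.20 (SE 0.14, limma adjusted p = 0.00690). CG14879 on 3R rose by 2.90 (SE 0.20, limma adjusted p = 0.0154) from 3.81, close to the median signal of all probe sets (3.67). The gene mth on 3L, which encodes the G protein-coupled receptor Methuselah, known for its effect on adult lifespan, rose by 2.55 (SE 0.21, limma adjusted p = 0.0258). Ir76a, a member of the ionotropic chemoreceptor family, rose by 1.77 from 3.49, and CG3032 on the X rose by 1.30, to 6.95 ± 0.10 from 5.65 ± 0.14. Their limma adjusted p were 0.0181 and 0.0342. The control levels of Cyp12a4, CG14879 and Ir76a were not shown to be above background, and RMA compresses differences there, so folds of these genes are those of the deposited values and not of the transcripts.

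The fallen genes were led by CG14314 (3R, 18216142 to 18218014), at 4.70 ± 0.42 in brakeless and 9.31 ± 0.44 in control embryos (SD, n = 3 each), a log2 difference of -4.61 (SE 0.30, limma adjusted p = 0.0154). CG17560 fell by 2.99 (SE 0.29) and Rcd-1r, a relative of the CCR4-NOT subunit gene Rcd-1, fell by 2.89 (SE 0.22), with limma adjusted p of 0.0371 and 0.0181. CG2993 fell by 2.85 and ord, which is needed for sister chromatid cohesion in meiosis, fell by 2.83. In each of these 4 genes the brakeless mean, between 3.02 for CG17560 and 4.11 for ord, was near the lower end of the array's scale, where RMA compresses differences. Cyp6d2, another cytochrome P450, went from 7.16 ± 0.26 to 4.84 ± 0.06, a difference of -2.32 (SE 0.15, limma adjusted p = 0.0154). The gene cGlr2, which encodes a cGAS-like receptor of antiviral immunity, fell by 2.28 from 6.67 ± 0.15 to 4.39 ± 0.19 (limma adjusted p = 0.0154).

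The other 5 genes of the 12 that fell most were CG10089 (-2.08), CG10916 (-1.83), CG1894 (-1.76), CG32773 (-1.68) and CG11200 (-1.66), with limma adjusted p between 0.0154 and 0.0396. CG10916 lies on 2R at 18173669 to 18175725, within 1 Mb of sbb, and stood at 6.73 ± 0.31 against 8.56 ± 0.09. CG11200 read 6.60 ± 0.11 against 8.26 ± 0.09, far above the background. Both CG10089 and CG1894 have another probe set, dimmer over the 6 arrays, whose differences of -0.05 and -0.20 did not pass the test. With the mean of all probe sets they read -1.065 and -0.98 and were not called (limma adjusted p of 0.0898 and 0.122). Among all genes named by the rule, centring ended the calls of CG10089, CG32773 and CG17560 (limma adjusted p of 0.0589, 0.0553 and 0.0518). Trend and robust ended those of CG11200 (0.0559) and CG3032 (0.158). The filter at the 60th percentile also ended that of CG3032 (0.0633). The 4 remaining genes that fell were GLaz, a lipocalin, at -1.63, CG9119 at -1.62, CG1503 at -1.55 and CG17167 at -1.46. Of the called probe sets without a single name, 3 matched several genes and 1 was unnamed here, and all of these fell.

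**Figure D1:**
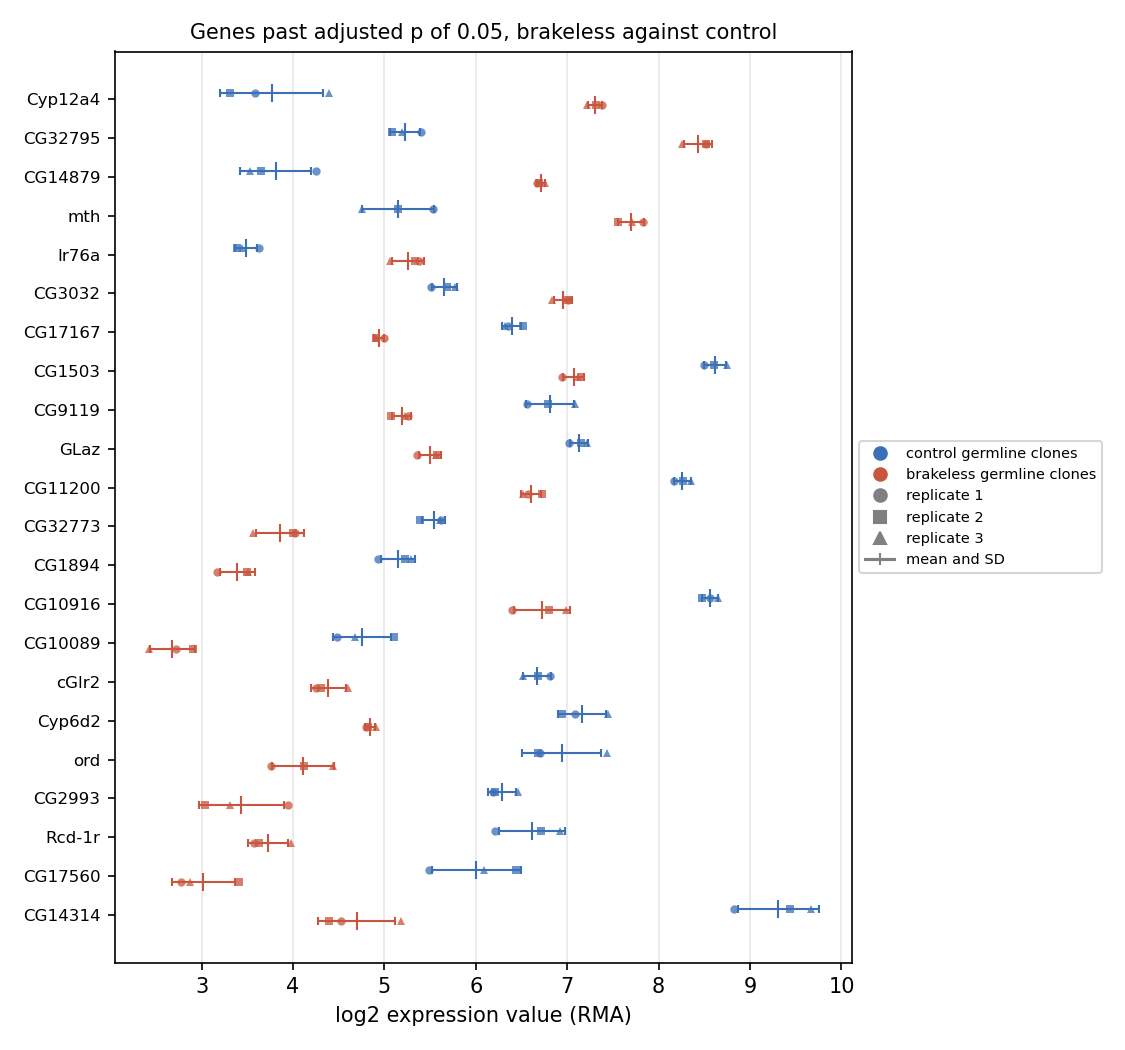
Log2 RMA values (horizontal axis) of the 22 genes past an adjusted p of 0.05, with control embryos in blue and brakeless embryos in red, 1 point per array shaped by replicate, and a bar for the mean and SD of each group (n = 3). The 6 genes at the top are higher in every brakeless array, from 3.54 for Cyp12a4 to 1.30 for CG3032, and the 16 below are lower in every brakeless array.

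Gap genes, the first zygotic segmentation genes, were compared because Brakeless is known to act in their regulation. None of the 11 measured gap genes passed the test, either over all probe sets or adjusted over the list alone. The smallest adjusted p over the list was 0.409 (limma). The log2 differences were 0.78 for hb (interval -0.47 to 2.03), 0.35 for Kr (interval -1.61 to 2.32), -0.28 for kni (interval -0.66 to 0.11), 0.28 for gt (interval -0.90 to 1.45), -0.39 for tll (interval -0.80 to 0.03) and -0.27 for hkb (interval -1.003 to 0.46). The limma adjusted p was 0.998 for all 6 genes. The intervals of hb and Kr leave room for large changes, and RNA of pooled embryos does not show where a gene is expressed. Control replicate 3 read 7.94 for hb, 5.84 for Kr and 6.64 for gt, below the other control arrays, which read at least 9.47, 8.43 and 8.12. Without control replicate 3 the differences were 0.18 for hb, -0.57 for Kr and -0.23 for gt, so that the last 2 turned sign. The list's mean difference was 0.07 and its median -0.06, and the camera test, which pointed down, had an adjusted p of 0.802. Without control replicate 3 the list's mean was -0.24 (camera adjusted p = 0.0568).

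**Figure D2:**
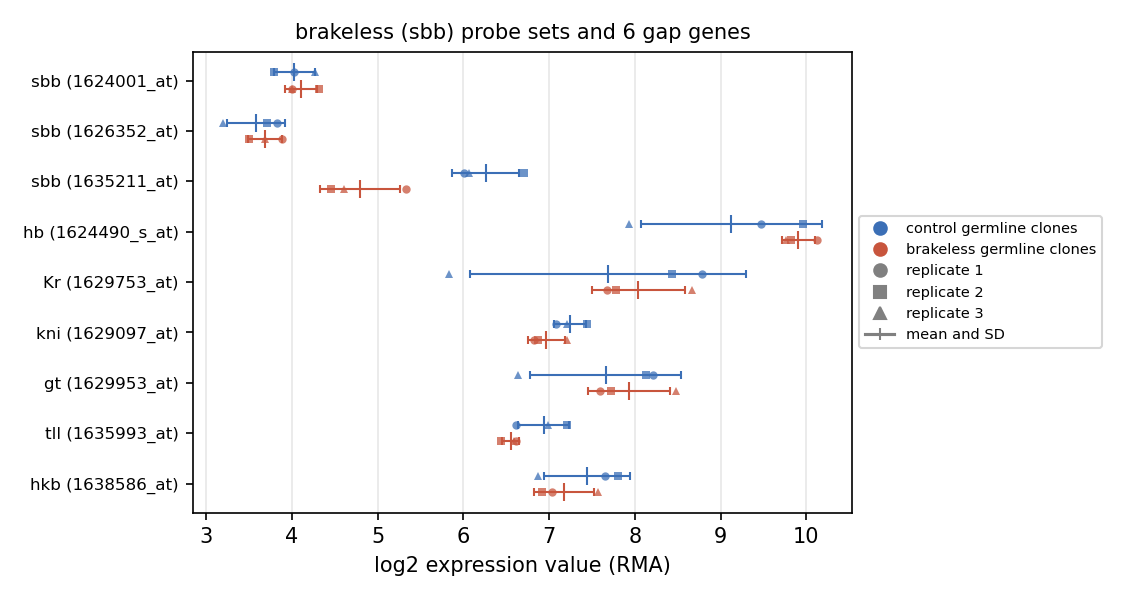
Log2 RMA values (horizontal axis) of the 3 sbb probe sets and of 6 gap genes, with control embryos in blue and brakeless embryos in red, 1 point per array shaped by replicate, and a bar for the mean and SD (n = 3). Probe set 1635211_at of sbb is lower in all brakeless arrays, by 1.46 on average, and for hb, Kr and gt control replicate 3 (7.94, 5.84 and 6.64) lies below the other 5 arrays.

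Genes of cellularization, the step at which membranes enclose the blastoderm nuclei, had a lower list mean in brakeless embryos, but the arrays overlapped. Of the 8 measured, 7 had negative differences, and the mean was -0.41 and the median -0.35. At the preset correlation the list passed camera with an adjusted p of 0.0311. Relative to the list's mean over all arrays, brakeless replicate 3 (0.09) lay above control replicate 3 (-0.08). An exact permutation test on the list means of the arrays gave p = 0.2, and the smallest p it allows is 0.1. With an estimated correlation the camera adjusted p was 0.976. No member passed over all probe sets and 1 fell when adjusted over the list alone: Sry-alpha, which organizes actin at the cellularization front, at 9.59 in brakeless and 10.6 in control embryos, a difference of -1.03 (SE 0.15, limma adjusted p = 0.00326 over the list and 0.114 over all probe sets). Other members were nullo at -0.63 (SE 0.25), Z600, a mitotic inhibitor, at -0.67 (SE 0.51), bnk at -0.40 (SE 0.19) and slam at -0.10 (SE 0.15), none past the test. The list's camera adjusted p was 0.215 without brakeless replicate 1, 0.0660 without control replicate 1 and 0.197 without control replicate 2. Over all alternatives that used camera it ran from 0.000446 to 0.976. The adjusted p of directional fry was 0.989 and that of mixed fry 0.0161.

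Maternal axis genes, transcripts loaded by the mother to pattern the embryo, had a higher list mean in brakeless embryos, but the arrays overlapped. Of the 18 measured, 14 had positive differences, with a mean of 0.35 and a median of 0.33. At the preset correlation the camera adjusted p was 0.0311. Relative to the list's mean over all arrays, brakeless replicate 3 (-0.004) lay below control replicate 2 (0.11). The exact permutation test on the list means of the arrays gave p = 0.2, and the smallest p it allows is 0.1. With an estimated correlation the camera adjusted p was 0.976. No member passed the test, either over all probe sets or adjusted over the list alone. Examples were trk at 0.42 (SE 0.13), bcd at 0.52 (SE 0.28), osk at 0.51 (SE 0.30) and spz at 1.08 (SE 0.76). Control replicate 3 lay 0.52 below the list's mean over the 6 arrays (a deviation of -0.52), and without it the mean difference was 0.18 with a camera adjusted p of 0.0677. The camera adjusted p was 0.239 without brakeless replicate 1 and 0.0640 without control replicate 1. Over all alternatives that used camera it ran from 0.00376 to 0.976. The adjusted p of directional fry was 0.989 and that of mixed fry 0.814. The camera adjusted p was 0.0774 after quantile normalization again, 0.0690 after centring and 0.0686 with array weights. It was 0.110 with the 60th percentile filter and 0.0839 with the mean of all probe sets. With the cleared maternal covariate, added after the data were seen, it was 0.408 and the mean was 0.10. The list behind that covariate shares bcd, nos and osk with this list, so part of that drop may be built in.

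Across the other 23 lists no shift passed the test, no member passed over all probe sets, and 1 member, in the ribosomal protein list, fell when adjusted over the list alone. Pair-rule genes, which set the alternate segments, had a mean of 0.31 with 7 of 8 positive (camera adjusted p = 0.248). Segment polarity genes had 0.12 (0.753), homeotic genes -0.02 (0.769), neurogenic ectoderm genes 0.29 (0.368), mesectoderm and Notch response genes 0.15 (0.802), mesoderm genes 0.09 (0.513) and terminal and endoderm genes 0.08 (0.996), each value being the mean log2 difference with the camera adjusted p after it. The sign of the homeotic mean was turned by both scaling alternatives, and its median of 0.02 and test pointed up. Homeotic genes averaged 4.29 in brakeless and 4.31 in control embryos, toward the lower end of the scale, where RMA compresses differences. The terminal median was -0.02, while its test pointed up. Control replicate 3 was the lowest array in each of these lists, with deviations from -1.09 for the neurogenic to -0.46 for the homeotic genes. Without it the positive means turned, to -0.15 for pair-rule, -0.26 for segment polarity, -0.18 for neurogenic, -0.16 for mesectoderm, -0.19 for mesoderm and -0.24 for terminal genes, of which the terminal list then passed (camera adjusted p = 0.0224). Dorsal ectoderm and amnioserosa genes, many of them targets of the BMP ligand Dpp, had -0.09 (camera adjusted p = 0.513), and -0.23 without control replicate 3, where the list passed (0.045). Within that list scw, a BMP ligand, read 7.88 against 8.66, a difference of -0.77 (SE 0.17, limma adjusted p = 0.0760 over the list alone and 0.407 over all probe sets).

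The remaining lists of maternal and germ line transcripts had mostly positive differences, and none passed the test. The 9 germ plasm and pole cell genes, among them tud at 1.11 (SE 0.82) and osk at 0.51 (SE 0.30), were all positive, with a mean of 0.46 and a camera adjusted p of 0.0890. Zelda and other early activators, led by Stat92E at 0.86 (SE 0.60) and zld at 0.69 (SE 0.49), had 7 of 7 positive and a mean of 0.46 (camera adjusted p = 0.114). Without control replicate 3, where these lists deviated by -1.01 and -1.26, the means were 0.08 and -0.05. Without control replicate 2 both lists passed, at 0.75 and 0.78 (camera adjusted p of 0.00376 and 0.0146), as did germ plasm genes without brakeless replicate 3 (0.0124) and early activators without brakeless replicate 2 (0.0449). Cleared maternal transcripts, which are destroyed as the zygote takes over, had a mean of 0.33 and a median of 0.45 (camera adjusted p = 0.197), with smg at 0.78 (SE 0.58). Their mean was 0.074 without control replicate 3 (camera adjusted p = 0.603), and 0.51 without control replicate 2, where the list passed (0.0316). Muscle genes of older embryos had 8 of 8 negative and a mean of -0.67 (camera adjusted p = 0.0750), and their list deviations were -1.39, -0.23 and 0.60 in the brakeless arrays and 0.52, 1.13 and -0.64 in the control arrays. The muscle mean was -0.15 without brakeless replicate 1 (camera adjusted p = 0.733) and -0.28 without control replicate 2 (0.527), and the list passed at -1.14 without brakeless replicate 3 (0.00309) and at -1.16 without control replicate 3 (0.000237). Neuron genes of older embryos had -0.17 (0.472) and hemocyte, trachea and cuticle genes -0.10 (0.513), again with the camera adjusted p after the mean. The neuron list averaged 3.81 in brakeless and 3.98 in control embryos, near the median of all probe sets (3.67), so a shift could be hidden. The hemocyte list passed at -0.29 without control replicate 3 (0.045) and its mean was 0.059 without control replicate 2 and 0.0097 without brakeless replicate 1.

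Lists of stress, immunity and basic cell functions gave no shift past the test with all 6 arrays. The mean differences with their camera adjusted p were 0.08 (0.769) for co-repressors, -0.11 (0.996) for heat shock genes, 0.04 (0.988) for apoptosis genes, -0.17 (0.567) for antimicrobial peptide genes, 0.19 (0.208) for cell cycle genes and -0.09 (0.716) for glycolysis genes. The cell cycle list passed at 0.32 without brakeless replicate 3 (0.0124) and at 0.33 without control replicate 2 (0.0316). Signs turned for glycolysis genes without brakeless replicate 3 (0.22) or control replicate 3 (0.067), for apoptosis genes without the same arrays (-0.12 and -0.19), and for co-repressors without brakeless replicate 1 (-0.071) or control replicate 3 (-0.090). Genes of sex determination and dosage compensation had -0.08 (0.605), and 0.020 and 0.022 without control replicates 1 and 2. The heat shock mean was 0.0015 without brakeless replicate 2 and 0.011 without control replicate 2. Follicle cell and yolk genes, markers of maternal tissue, had -0.03 (0.769), a sign that turned after quantile normalization was applied again, and without brakeless replicate 1 (0.010) or control replicate 3 (0.052), and a median of 0.02. The apoptosis mean was positive while its test pointed down. The antimicrobial peptide list averaged 3.73 in brakeless and 3.90 in control embryos, and the follicle cell list 3.79 and 3.82. Both lay near the median of all probe sets (3.67), where RMA compresses differences, so a shift could be hidden. For heat shock genes Hsp26 read 0.54 higher (SE 0.17) and Hsp68 -1.07 (SE 0.39), neither past the test. Among 41 ribosomal protein genes the mean was -0.23 and the median -0.03 (camera adjusted p = 0.513). Within it RpS10a, a duplicate of RpS10b, fell when adjusted over the list alone: its 3 brakeless arrays read 4.64, 4.77 and 8.48 and its control arrays 12.4, 11.4 and 12.2, a difference of -6.06 (SE 1.06, limma adjusted p = 0.0486 over the list and 0.206 over all probe sets).

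**Figure D3:**
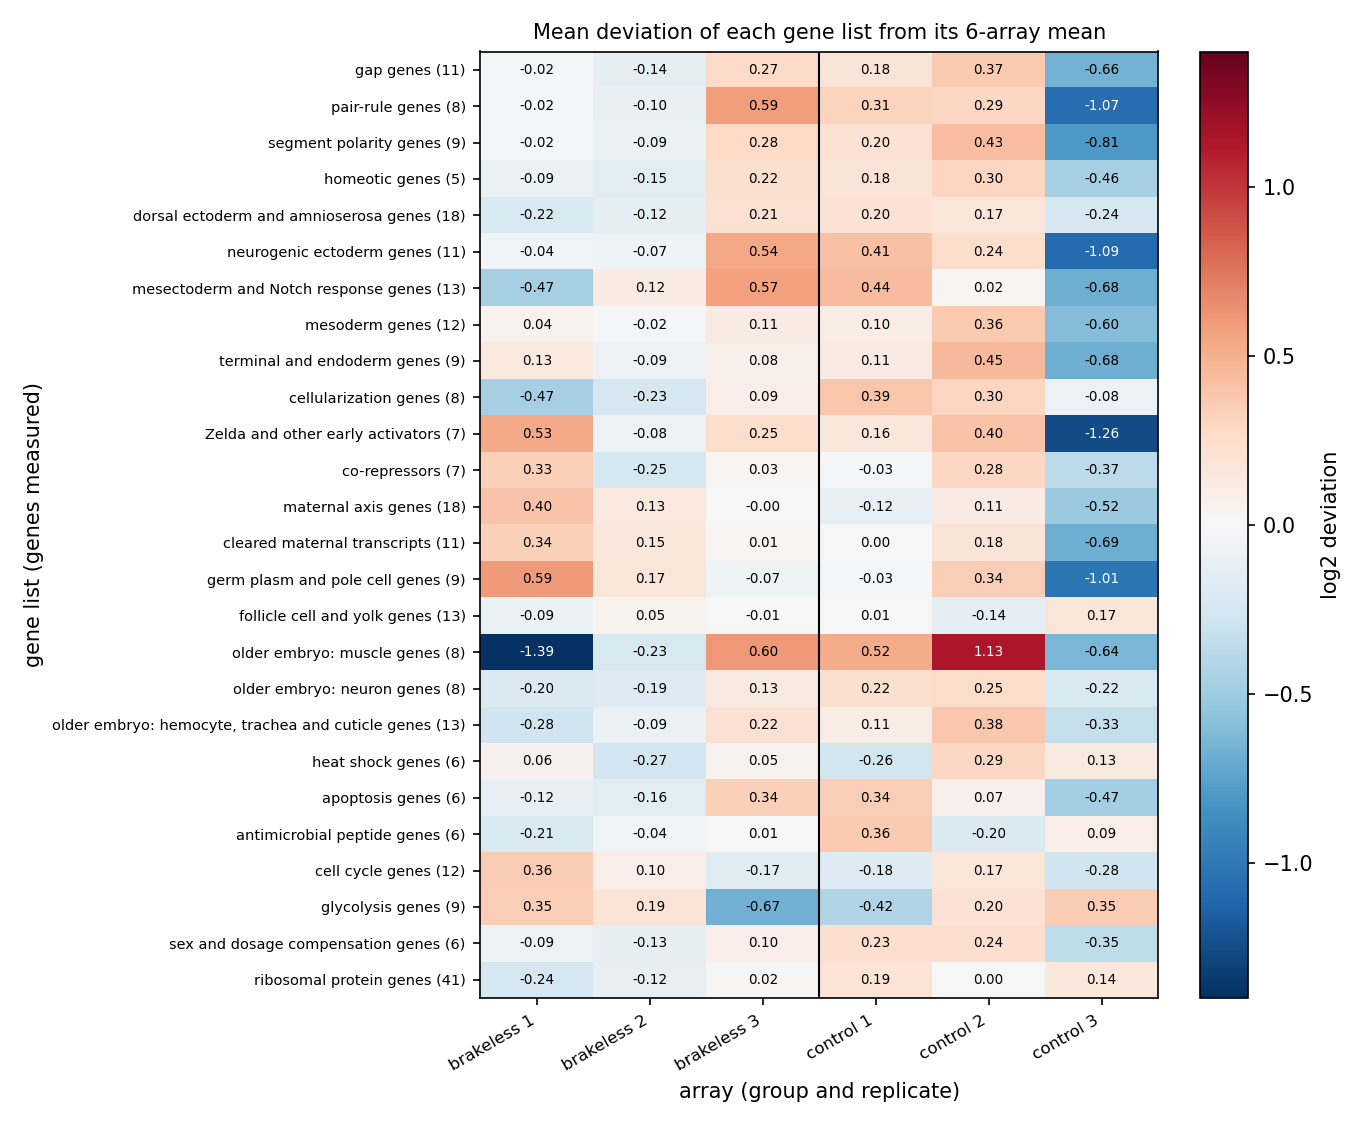
Mean log2 deviation of each of the 26 gene lists (vertical axis, with the number of genes measured) from its mean over the 6 arrays (horizontal axis, brakeless arrays left of the line and control arrays right of it), with the value printed in each cell and coloured red above and blue below 0. Control replicate 3 is lowest for the pair-rule (-1.07), neurogenic (-1.09) and early activator (-1.26) lists, and for muscle genes brakeless replicate 1 (-1.39) and control replicate 2 (1.13) lie farthest apart.

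By the cross, all brakeless embryos carried the mutagenized second chromosome of their mothers, and some also carried the CyO balancer of their fathers. The chromosomes of the called genes were therefore compared with those of all genes. Of 21 called genes with a position, 7 lay among the 4632 on 2L and 2R and 14 among the 7256 elsewhere, an odds ratio of 0.783 (95% interval 0.267 to 2.07, Fisher's exact p = 0.661, two-sided). The ratio lay above 1 with array weights (1.09), with the filters at the 40th and 60th percentile (1.12 and 1.21) and without brakeless replicate 3 (1.04), so its direction is not settled. On 2R itself there were 6 among 2427 genes (odds ratio 1.56, interval 0.496 to 4.26, Fisher's exact p = 0.413). Within 1 Mb of sbb 1 of 251 genes was called, CG10916, and CG11200 was the 1 called among 204 genes at 1 to 2 Mb. Cyp6d2 and ord lay 2 to 5 Mb away, and cGlr2 and GLaz farther. Genes are not independent replicates in these tests.

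The spread between arrays was described next. The first principal component held 49.7% of the variance and placed control replicate 3 at 77.9 and the other 5 arrays between -31.1 and -6.94. The spiked hybridization controls averaged 11.3 ± 0.96 in brakeless and 11.2 ± 0.39 in control arrays (SD, n = 3 each, exact permutation p = 1, two-sided), and the 3' minus 5' difference of 3 control transcripts averaged 1.68 ± 0.07 and 1.62 ± 0.12 (n = 3 each, exact permutation p = 0.7). With 3 arrays against 3 the smallest p an exact test allows is 0.1. The spike mean correlated with the second component at Pearson's r = -0.81 over 6 arrays (exact permutation p = 0.0556, 0.181 adjusted over 2 relations and 2 methods) and Spearman's rho = -0.71 (exact permutation p = 0.136), and without the 2 arrays of most extreme spike means r was -0.38 and rho -0.20, so the relation rests on those arrays. With the first component Pearson's r was -0.40 (exact permutation p = 0.375, also 0.375 adjusted) and Spearman's rho -0.71 (exact permutation p = 0.136, 0.181 adjusted), and without those 2 arrays r was -0.68 and rho -0.80 over 4 arrays. Neither relation passed.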

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

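The fits with the hybridization spike mean or the mean of the cleared maternal transcripts as a covariate were chosen after the data were seen; all other alternatives were planned. The number of calls and their membership moved with the alternatives. The called probe sets kept their direction in the refits that tested them (23 of the 26 with the filter at the 60th percentile), but their arrays do not overlap and their differences far exceed the shifts of the scalings, so this says nothing about stability. With 3 arrays per group and 2.05 prior degrees of freedom, each call leans on the spread of few arrays, and probe sets near the lower end of the scale carry compressed differences. The cause of each change below was not tested, except where fewer arrays, fewer probe sets or a stricter null are the alternative itself.

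Calls higher, lower and in total were 12, 34 and 46 with trend and robust (20 shared with the 26), 19, 55 and 74 with array weights (26 shared), 8, 15 and 23 with quantile normalization again (16 shared), 2, 1 and 3 with the cleared maternal covariate (3 shared), and 2, 4 and 6 with treat against 1.5-fold. Array weights give less weight to an array that departs from the fit. Leaving out 1 array gave 0 to 10 higher, 0 to 23 lower and 0 to 33 in total. The spike covariate gave 20 calls (15 shared), left 100.3% of the median called difference (98.7% to 101.5%) and itself passed for 0 probe sets, so it cannot settle whether unequal hybridization contributed. The cleared maternal covariate left 97.6% of the median called difference (87.6% to 110%) with standard errors 1.10 times as large, and itself passed for 0 probe sets.

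Same-numbered arrays did not deviate together: the correlations of their deviations were -0.40, -0.23 and -0.32. No brakeless array correlated best with the control array of its own number. The deviations gave no sign of pairing by number, but they cannot exclude that arrays were collected or processed in pairs. With the replicate number as a block limma called 0 higher, 0 lower and 0 in total (678 at an unadjusted p under 0.05), and the germ plasm list passed at a mean of 0.46.

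With array weights the mean log2 difference turned for the gap (-0.16), pair-rule (-0.070), segment polarity (-0.14), neurogenic (-0.093), mesectoderm and Notch response (-0.055), mesoderm (-0.066), terminal (-0.12), co-repressor (-0.11), follicle cell (0.030), apoptosis (-0.20) and glycolysis (0.18) lists, and for sbb probe set 1626352_at (-0.099), Kr (-0.33) and gt (-0.12). The maternal axis list (0.26) no longer passed and the muscle list (-0.84) did. With the cleared maternal covariate it turned for the gap (-0.25), pair-rule (-0.13), segment polarity (-0.28), neurogenic (-0.16), mesectoderm (-0.041), mesoderm (-0.23), terminal (-0.30), early activator (-0.15), co-repressor (-0.17), germ plasm (-0.063), follicle cell (0.080) and apoptosis (-0.15) lists, and for 1626352_at (-0.12), Kr (-0.53) and gt (-0.18). There the maternal axis list (0.10) no longer passed, while the muscle list (-1.02) and the turned terminal list (camera adjusted p = 0.0205) did. The cleared maternal list shares genes with the maternal axis and germ plasm lists, so their changes there may be partly built in.

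The muscle list also passed with trend and robust (-0.67) and the spike covariate (-0.77), and the germ plasm list with the spike covariate (0.49). Quantile normalization again turned the homeotic (0.042) and follicle cell (0.0030) means, centring turned the homeotic mean (0.0090), and the filter at the 60th percentile turned the apoptosis mean (-0.037). The maternal axis list missed the threshold after quantile normalization (0.33), centring (0.38), the 60th percentile filter (0.35) and the mean of all probe sets (0.28), and with an estimated correlation or either form of fry (0.35). The cellularization list missed it with the 60th percentile filter, an estimated correlation or directional fry (-0.41 in each). The mean of the sbb probe sets was -0.43. The second chromosome odds ratio was 1.09 with array weights, 1.12 and 1.21 with the 40th and 60th percentile filters, and the mean correlation of control replicate 3 was 0.938 and 0.861 with those filters.

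Leaving out 1 array moved mean list differences over these ranges: gap -0.24 to 0.28, pair-rule -0.15 to 0.54, segment polarity -0.26 to 0.36, homeotic -0.25 to 0.13, dorsal ectoderm -0.23 to 0.0017, neurogenic -0.18 to 0.57, mesectoderm -0.16 to 0.42, mesoderm -0.19 to 0.30, terminal -0.24 to 0.33, cellularization -0.55 to -0.27, early activators -0.050 to 0.78, co-repressors -0.090 to 0.24, maternal axis 0.18 to 0.50, cleared maternal 0.074 to 0.51, germ plasm 0.075 to 0.75, follicle cell -0.11 to 0.052, muscle -1.16 to -0.15, neuron -0.32 to -0.089, antimicrobial peptide -0.31 to -0.026, ribosomal protein -0.29 to -0.16, hemocyte, trachea and cuticle -0.29 to 0.059, heat shock -0.26 to 0.011, apoptosis -0.19 to 0.22, cell cycle 0.058 to 0.33, glycolysis -0.32 to 0.22, and sex determination -0.27 to 0.022. Some lists that missed the threshold passed camera with an array left out, with these adjusted p: muscle without brakeless replicate 3 (0.00309) or control replicate 3 (0.000237), germ plasm and cell cycle without brakeless replicate 3 (0.0124 for both) or control replicate 2 (0.00376 and 0.0316), early activators without brakeless replicate 2 (0.0449) or control replicate 2 (0.0146), cleared maternal without control replicate 2 (0.0316), and dorsal ectoderm and hemocyte (0.045 for both) and terminal (0.0224) without control replicate 3. For single probe sets the ranges were 0.18 to 1.20 for hb, -0.57 to 0.91 for Kr, -0.40 to -0.17 for kni, -0.23 to 0.55 for gt, -0.55 to -0.25 for tll, -0.56 to -0.087 for hkb, -0.037 to 0.20 for 1624001_at and -0.084 to 0.23 for 1626352_at, and the second chromosome odds ratio ran from 0.627 to 1.04 (no value where 0 genes were called).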

Other observations

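The lists and tests of cytochrome P450 and glutathione S-transferase genes, of testis markers and of control replicate 3, the test of genes off the second chromosome, and the ribosomal protein examples were chosen after the result was seen; the tests of other splits, embryo age and the second chromosome were planned. Genes of 2 detoxification families were tested for small p. Cytochrome P450s oxidize, and glutathione S-transferases conjugate, foreign and endogenous small molecules. Of 117 measured genes of these families, 10 (8.55%) had an unadjusted p under 0.01, against 248 of 11865 other genes (2.09%), an odds ratio of 4.38 (95% interval 2.02 to 8.50). A permutation over genes matched on mean signal gave p = 0.00030. Of the 10, only Cyp6d2, which fell, and Cyp12a4, which rose, passed the test over all probe sets. The rest did not pass: GstD5 stood at -1.35 (SE 0.14, limma adjusted p = 0.0533), GstE9 at -1.58 (SE 0.21), Cyp6a13 at -2.39 (SE 0.33), GstD2 at -1.10 (SE 0.17), Cyp9c1 at -1.32, GstE7 at -1.42, Cyp4p2 at -0.52 and Cyp12c1 at 1.29. The difference was negative for 8 of the 10. Genes of these families lie in clusters of relatives, so they are not independent, and cross-hybridization between relatives was not tested. The families were noticed among the same genes that were then tested, so a difference in their expression between the pools is a hypothesis, and it may come from the stocks as well as from the mutation, since these genes are known to vary between strains and the design does not separate these sources.

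In the ribosomal protein list, which did not shift (camera adjusted p = 0.513), the members with the smallest p after RpS10a (-6.06) were RpL22-like at -1.51 (SE 0.36), RpL37-2 at -0.82 (SE 0.28) and RpS19b at -0.86 (SE 0.35), none of them past the test adjusted over the list alone. Whether duplicated genes differ more often than other members was not tested. RpS10a itself spread widely among the brakeless arrays, at 4.64, 4.77 and 8.48.

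Several explanations for the 26 called probe sets were tested. With only 10 splits of the arrays into 3 and 3, of which 1 gave as many calls, no share under 0.05 can be reached; the real split gave 26 and the highest of the others 0. A younger brakeless pool could raise cleared maternal transcripts and lower older markers. Their medians were 0.45 (interval over genes -0.22 to 0.52) and -0.16 (interval over genes -0.35 to -0.10), which neither meets nor excludes such an age difference. These intervals were drawn over genes, so they do not measure the spread between pools. Without control replicate 3 the mean of the cleared maternal transcripts was 0.074, against 0.33 with all 6 arrays. Sequence or expression differences of the second chromosome would crowd the calls there, and the odds ratio of 0.783 (interval 0.267 to 2.07) leaves this open, while 66.7% of called genes lay off that chromosome, against 61.0% of all genes. Differences between the stocks and effects of the mutation cannot be told apart for those genes, because each genotype came from 1 kind of cross.

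Control replicate 3 stood apart from the other 5 arrays. RNA degradation is argued against by its 3' minus 5' difference of 1.504, below the 1.59 to 1.75 of the others, and a different hybridization signal by its spike mean of 10.9, inside their range of 10.3 to 12.2. Unfertilized eggs or undeveloped embryos would spare maternal transcripts, but these deviated by a median of -0.63 (interval over genes -0.93 to -0.06). Zygotic patterning genes deviated by -0.66 (interval over genes -1.03 to -0.47), while all genes had a median of 0.08. These intervals describe genes within that array and not a spread between arrays. Cleared maternal transcripts (-0.69) and the muscle (-0.64), neuron (-0.22) and hemocyte (-0.33) genes of older embryos all lay below their 6-array means there. For muscle genes brakeless replicate 1 was lower still (-1.39). These lists do not point to a younger or to an older pool. The array's median (3.73) was the highest and its upper quartile (7.57) the lowest of the 6 arrays. A difference in signal range, or a biological difference between that pool and the others, was not tested and stays open.

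Because Rcd-1r, known for its expression in testis, fell, and aly, a regulator of testis genes, read 4.27 in control and 2.89 in brakeless embryos without passing the test, testis or sperm RNA in the control pools was considered as a possible explanation. Over 43 testis markers the median difference was 0.018 (interval -0.02 to 0.05), with 21 lower, 22 higher and 0 past the limma threshold. Only 9 of them lay above the median probe set in control arrays, so the median and the split mostly reflect values near the background. Those 9 differed by -1.38 (aly), -0.60 (bol), -0.49 (mia), -0.47 (CG31542), -0.21 (Pp2C1), -0.02 (Mst98Ca), 0.06 (ATPsynbetaL), 0.07 (hale) and 0.78 (Taf12L). Abundant testis transcripts such as betaTub85D (2.76), dj (2.41) and ProtA (2.42) stayed at the bottom of the scale in control arrays, which argues against such RNA.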
